A study of Arabidopsis thaliana with 10 samples.

How the data were processed

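Whole seedlings were grown for 7 days on half-strength MS medium with 0.8% agar at 23 °C in 16 hours of light and 8 of darkness, and libraries were made with a stranded mRNA kit, per the labels. The labels name 10 libraries, 2 for each of 5 genotypes. Per the submitters' processing notes the tools were TopHat2, Cufflinks and Cuffdiff and the build TAIR10; their versions, settings and roles are not given in the sources used here, nor is whether counting used the strand. The deposited table holds FPKM (fragments per kilobase of transcript, scaled to the mapped fragments), with 1 value per gene and genotype made by the authors. Each mutant column names both of its libraries, while the wild-type column names none and was taken as Col. How libraries were combined is not given in the sources used here. FPKM sums were 955700 in Col, 1153300 in hda9, 1142810 in hos15, 1326090 in pwr and 1177220 in the double mutant. No counts can be had from these values, so depth, counting intervals and detection limits are unknown. All 271 organelle rows are listed at 0 in every column, so a 0 is reported as listed and no fold is given against it. Another 239 rows join several loci under 1 label, of which 212 were kept.

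The tests planned before the data were examined were moderated linear models on log2(FPKM + 1) over 10 libraries, with camera and fry for gene lists. They could not be used, because the values are 1 per genotype. The comparisons, transformation, pseudocount of 1 and gene lists were kept as planned. The planned filter, FPKM of at least 1 in at least 2 of the 10 libraries, was applied to the 5 columns instead. A gene at that level in only 1 column was therefore left out. In place of an adjusted p under 0.05, a fixed rule of size was used: a difference of at least 1 on the log2 scale (2-fold), on rows with FPKM of at least 1 in at least 2 of the 5 columns. No p-value is given, and a count under this rule describes these columns, not the genotypes. For each of 21 fixed lists and 10 annotation families with at least 5 measured members, the median log2 fold change was placed as a percentile among 10000 random lists of the same size, drawn from 20 bins of mean expression. This gave 108 percentiles over 27 lists and families, 24 of them below 2.5 or above 97.5. Random lists hold independently drawn genes, so the percentiles take no account of members that move together. Of 301 list members, 299 had a row and 233 were kept.

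Genes were named by a rule fixed beforehand, with the 2-fold rule in place of the test, the largest fold in place of the smallest p, and the condition on single libraries dropped. For each mutant against Col it took the 3 targeted genes, and, with FPKM of at least 2 in the higher column, the 6 largest rises and 6 largest falls with a symbol, 2 of each with or without a symbol, and up to 3 members per list. It took the 4 largest each way for the other contrasts and the 8 largest each way for genes shared by the 3 single mutants. Other list members are named only within the account of their list. Short RNAs that the rule picked are described as a class, with examples.

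Symbols, products, transcript length, GC and purine content came from an annotation of the TAIR10.1 assembly, matched by locus code for 32350 rows. Since that assembly is not stated to be the build of the files, no coordinates are given, and the chromosome is read from the locus code. Sequence-adjusted values are residuals of the log2 fold change on additive cubic splines (5 knots each) of transcript purine percentage, the highest purine percentage in a 100-nt window, log2 length and GC percentage. They were computed on kept protein-coding genes of at least 300 nt (18079 genes, 95.6% of the kept rows).

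Because all mutants were set against the same Col column, 100 simulations of unchanged columns with the scatter seen between hda9 and hos15 gave the chance correlation, covariance and overlap. Procedures were tested on simulated data first. In simulated columns standing for hda9 and Col, with 18912 genes, 98 of 100 genes changed by a log2 value of 1.5 were called on the right side. So were 100 of 100 changed by 2.5, and 92 of 18712 unchanged genes were called. The scatter was again that between hda9 and hos15 (standard deviation of log2 ratios 0.32), not that between hda9 and Col (0.56). Changed genes were drawn among the more strongly expressed, so recovery of weakly expressed genes was not tested. Of 300 random lists of unchanged genes 13 lay beyond the 2.5th or 97.5th percentile. Their genes were simulated independently, so this does not cover lists whose members move together. With a purine trend added to 18079 genes, 592 of 17879 unchanged genes were called before and 108 after adjustment, and 199 of 200 changed by 2 were called after it. The added trend was linear, and the changed genes were drawn without regard to purine content. Whether the adjustment spares real falls concentrated in purine-rich genes was therefore not tested.

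Alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, median-ratio scaling and quantile normalization, all planned, and 3 chosen after seeing the data: a 3-fold threshold, protein-coding transcripts of at least 300 nt, and sequence adjustment. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with figures by matplotlib 3.10.9. The table has 0 columns of per-sample values outside these genotypes.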

Results

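The data are mRNA profiles of 7-day-old whole Arabidopsis thaliana seedlings of 5 genotypes: the Columbia-0 wild type (Col), the single mutants hda9, hos15 and pwr, and the hda9 hos15 double mutant. HDA9 is a histone deacetylase, PWR (POWERDRESS) a SANT-domain protein and HOS15 a WD40-repeat protein, and the design text describes them as partners that bind one another. The labels list 2 libraries per genotype, 10 in all, harvested 12 hours after lights-on. The deposited table gives 1 FPKM value per gene and genotype, made by the authors over the libraries of that genotype. There were therefore no replicate values from which to take an error, and every difference below compares the authors' values per genotype without a replicate check. The read depth behind each value is unknown. Of 33297 rows, 18912 had an FPKM of at least 1 in at least 2 of the 5 columns and were compared, as log2(FPKM + 1), which understates the fold of weakly expressed genes. A gene is called higher or lower below when it differs at least 2-fold on this scale.

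The first question was whether each mutant column lacked the RNA of its mutated gene. HDA9 (AT3G44680, chromosome 3) stood at 7.79 FPKM in Col, 1.70 in hda9 and 1.76 in the double mutant, with 10.7 in hos15 and 10.9 in pwr. PWR (AT3G52250, chromosome 3) stood at 8.38 FPKM in Col and 2.18 in pwr, and between 9.76 and 12.1 in the other mutants; it overlaps an antisense gene. HOS15 (AT5G67320, chromosome 5) stood at 16.2 FPKM in Col, 2.16 in hos15 and 1.89 in the double mutant. HOS15 was also low in hda9, at 4.37 FPKM, and in pwr, at 3.17 FPKM, which carry no mutation in it according to the labels. The HOS15 transcript is 57.9% purine, and transcripts of that composition were low in all the mutant columns. After adjustment for transcript sequence the log2 fold change of HOS15 was -0.37 in hda9 and -0.37 in pwr, against -1.36 in hos15 and -1.46 in the double mutant. Of 9 other histone deacetylase genes, 7 were measured and none differed 2-fold from Col in any mutant. HDA6 lay between 9.99 and 13.1 FPKM and HDA19 between 39.5 and 45.8 FPKM over the 5 columns.

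**Figure D1:**
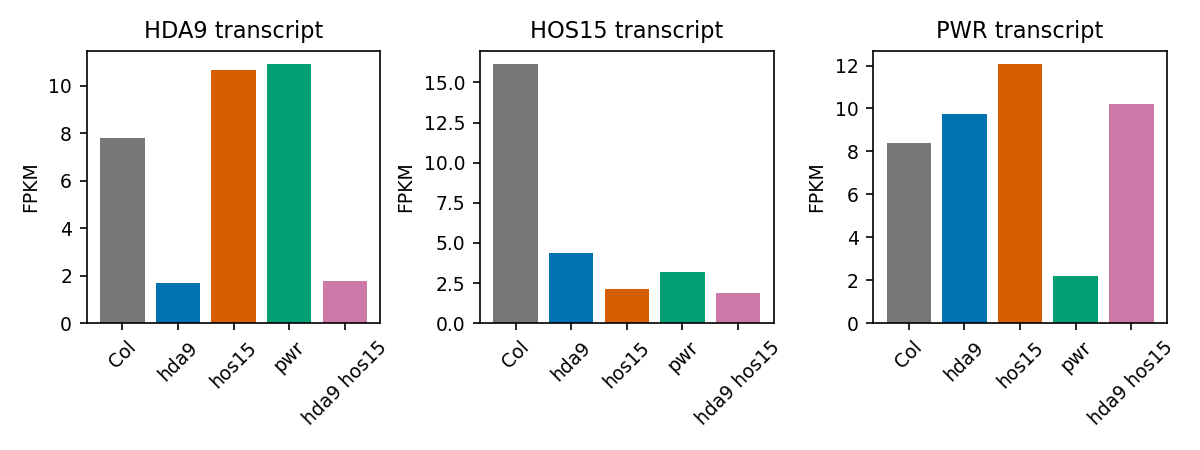
FPKM (vertical axes) of HDA9, HOS15 and PWR in the 5 genotypes, 1 bar for each of the authors' values, with no replicate error. Each gene is lowest or near its lowest in its own mutant, and HOS15 is also low in hda9 (4.37) and pwr (3.17) against 16.2 in Col.

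Transcript sequence moved with genotype in these columns and is given here because it touches every comparison with Col. Among 18079 protein-coding genes with transcripts of at least 300 nt, the log2 fold change against Col went down as the purine (A + G) percentage of the transcript went up. Spearman's rho across genes was -0.47 in hda9, -0.42 in hos15, -0.53 in pwr and -0.46 in the double mutant; genes are not independent replicates. The 232 genes over 58% purine had median log2 fold changes of -1.14 in hda9, -0.90 in hos15, -1.51 in pwr and -0.997 in the double mutant, and the 1237 genes of up to 46% purine had medians of 0.31, 0.22, 0.39 and 0.32 in the same order. Purine content, length and GC content together accounted for 35.1% of the variance of the log2 fold changes in hda9, 29.1% in hos15, 42.7% in pwr and 34.7% in the double mutant. Values called sequence-adjusted are what was left after these trends were removed, a step chosen after the data were seen.

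**Figure D2:**
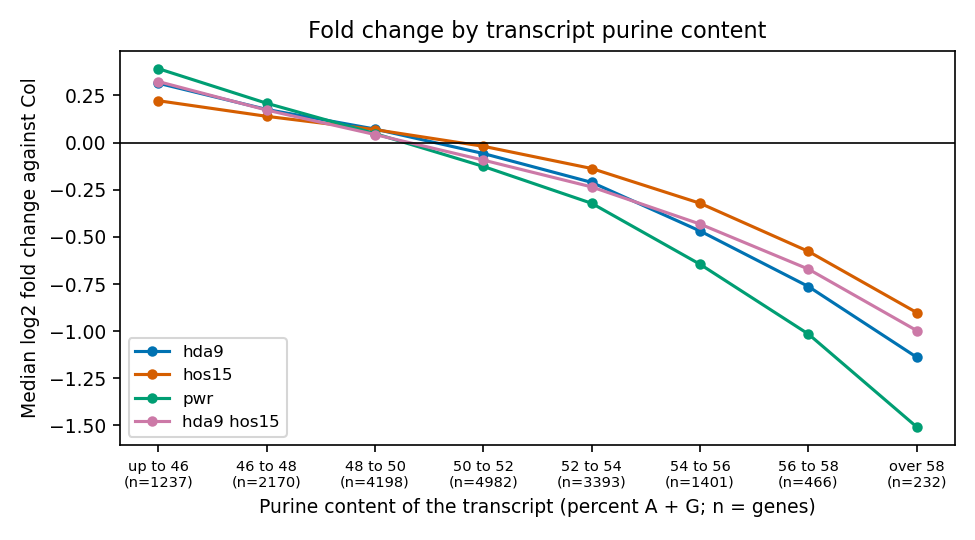
Median log2 fold change against Col (vertical axis) of protein-coding genes grouped by the purine percentage of their transcript (horizontal axis, with the number of genes), 1 line per mutant. All 4 lines go down with purine content, to -1.51 in pwr and -0.90 in hos15 for genes over 58% purine.

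The comparison of hda9 with Col asked which transcripts differ without HDA9. Among the largest differences on the higher side, STZ, a zinc-finger regulator of stress responses, stood at 12.8 FPKM in Col and 105 in hda9. The defensin transcript PDF1.2b stood at 9.51 and 67.2, and RTFL12, a small ROTUNDIFOLIA-like peptide gene, at 2.35 and 27.0. RSU1, a transcribed pseudogene that overlaps another gene on the same strand so that reads can be shared, stood at 2.76 and 30.3. Of 16 measured defensin genes, 8 were higher and 1 lower, and their median log2 fold change of 0.73 was at the 100th percentile of random lists matched on expression. These genes include near-identical copies between which reads can be split. Jasmonate-response genes had a median of 0.37 (99.8th percentile), with AOS, an enzyme of jasmonate synthesis, at 101 FPKM in Col and 222 in hda9, and 3 of 17 members higher. On the lower side, MFP1, which encodes a filament-like DNA-binding protein, stood at 50.5 FPKM in Col and 6.22 in hda9, the chromatin protein gene 3xHMG-box2 at 32.3 and 4.35, and the methyl-CpG-binding-domain gene MBD10 at 47.4 and 7.35. These 3 transcripts are 58.5%, 61.2% and 62.1% purine, and MFP1 and 3xHMG-box2 overlap an antisense gene. In all, 377 genes were higher and 849 lower. With sequence adjustment, among protein-coding genes, the split changed from 328 higher and 785 lower to 310 higher and 235 lower.

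In hos15 the same question gave a shorter list, with 232 genes higher and 469 lower. STZ stood at 70.9 FPKM and DIC2, a mitochondrial dicarboxylate carrier, at 70.7 against 14.7 in Col. ACS11, an ethylene synthesis gene, stood at 11.6 against 1.99, and the retroelement SADHU3-2 at 18.3 against 2.05. Lower transcripts included 3xHMG-box2 (4.87 FPKM) and RIP2 (2.58 against 17.7). Flavonoid and anthocyanin genes had a median log2 fold change of -0.33 (2.02nd percentile) with no member past 2-fold, and DFR, an anthocyanin enzyme, stood at 1.18 FPKM against 3.12. The sequence-adjusted split was 180 higher and 139 lower, against 185 and 417 for the same protein-coding genes before adjustment.

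The pwr column differed from Col at the most genes, 366 higher and 1427 lower. KIN2, a cold- and drought-induced gene, stood at 401 FPKM in Col and 1931 in pwr. HEI10, which acts in meiotic crossing-over, stood at 3.53 FPKM in Col and 18.8 in pwr and between 0.816 and 4.86 in the other mutants. HEI10 overlaps other genes on both strands. Lower transcripts included MFP1 (3.75 FPKM), NAI2, an endoplasmic reticulum body gene (98.3 in Col, 10.6 in pwr), and ABCF5 (60.1 and 6.21). The auxin-responsive gene IAA2 stood at 63.7 FPKM in Col and 13.0 in pwr, and the defence regulator EDS1 at 10.9 and 2.58, a log2 fold change of -1.73 that became -0.72 with sequence adjustment. A single 102-nt row, AT2G01021, took 13.9% of the FPKM sum in pwr and 4.13% in Col. Median-ratio scaling moved the median of all genes by 0.12 (log2) in pwr and gave 594 higher and 1157 lower, and quantile normalization gave 525 and 1042. Sequence adjustment gave 287 higher and 385 lower, from 310 and 1355.

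The hda9 hos15 double mutant was compared with Col and with each single mutant, to see whether loss of both genes goes beyond the loss of either. KIN2 stood at 2187 FPKM in the double mutant against 1397 in hda9 and 1310 in hos15, and KIN1 at 31.6 against 7.14 in Col. NCED3, an enzyme of abscisic acid synthesis, stood at 8.90 against 1.74 in Col, and ICL, the glyoxylate-cycle isocitrate lyase, at 20.2 against 4.81. CIPK20, a protein kinase gene, stood at 1.35 against 11.8, and ABCF5 at 10.9 against 60.1. Against Col 281 genes were higher and 739 lower; median-ratio scaling gave 373 and 589 and quantile normalization 344 and 530. Sequence adjustment gave 146 higher and 213 lower, from 227 and 673. Against hda9, 68 genes were higher and 282 lower, and against hos15, 56 were higher and 188 lower.

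Among the largest departures of the double mutant from the single mutants were stress-inducible transcripts that were high in hda9 and hos15. STZ stood at 28.2 FPKM in the double mutant, against 105 in hda9 and 70.9 in hos15. ERF6, an ethylene-response factor, stood at 18.7 in Col, 105 in hda9, 71.6 in hos15 and 21.3 in the double mutant. In the double mutant STZ and ERF6 lay above Col. Others that were high in hda9 lay below Col there: WRKY40 (5.14 in Col, 19.7 in hda9, 2.83 in the double mutant), TCH4, a touch-induced cell-wall enzyme (117, 270 and 57.0), PHI-1 (22.4, 81.6 and 16.5) and PDF1.2 (3.63, 23.3 and 2.72). The 170 genes higher in both hda9 and hos15 had median log2 fold changes of 1.54 and 1.29 there and 0.57 in the double mutant, where the sum of the single mutant values would be 2.75. The 406 genes lower in both had medians of -1.60 and -1.29, with -1.34 in the double mutant and -2.83 for the sum. Genes picked for large values in the single mutants fall short of them elsewhere through the picking alone. The 366 genes picked as higher in pwr had medians of 0.98 in hda9, 0.83 in hos15 and 0.95 in the double mutant, without a drop there. By the 2-fold rule 744 genes lay above and 665 below that sum. This split turned with a mean FPKM of at least 5 (307 and 496), with quantile normalization (679 and 709), at 3-fold (230 and 283) and, from 680 and 594 protein-coding genes, with sequence adjustment (359 and 580), and was level with median-ratio scaling (701 and 700). All 3 mutant columns in this sum are set against the same Col column, so its chance value enters each term.

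The single mutants were compared with one another because the 3 proteins were described as members of one complex. They differed far less from each other than from Col. Between hda9 and hos15, 68 genes were higher in hda9 and 72 lower. Between hda9 and pwr these numbers were 103 and 72, and between hos15 and pwr 162 and 65. The last pair of numbers became 88 and 89 with quantile normalization. Among protein-coding genes they went from 113 and 20 to 35 and 24 with sequence adjustment. HDA9 itself and HEI10 were among the largest of these differences with a symbol, beside short microRNA and small nucleolar RNA rows, several of them listed at 0 in a column. The standard deviation of log2 ratios over genes was 0.46 to 0.63 between a mutant and Col, and 0.32 to 0.36 between 2 mutants.

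In hda9, hos15 and pwr together, 105 genes were higher and 392 lower in all 3. Independent lists of these sizes would share 0.09 and 1.59 genes, and simulated unchanged columns set against one Col column shared 1.8 and 1.6, from 105 genes called per simulated mutant, far fewer than the 701 to 1793 called here. Those shared on the higher side included STZ, RTFL12, DIC2, ERF6 and the defensins PDF1.3 and PDF1.2b, and on the lower side MFP1, 3xHMG-box2, RIP2, MBD10, FP3, NAI2, ABCF5 and the histone chaperone gene FKBP53. FP3, a metal-binding protein gene, stood at 21.3 FPKM in Col, 3.17 in hda9, 3.54 in hos15 and 2.40 in pwr, but was under 2-fold in all 3 with sequence adjustment. With sequence adjustment 94 genes were higher and 81 lower, from 93 and 373, of which 61 and 68 were the same genes. Over the 6 pairs of mutants the log2 fold changes correlated across genes with a median Pearson r of 0.82 (0.77 to 0.85), where unchanged columns sharing a Col column gave 0.50. The median covariance was 0.24, against 0.05 in the simulation. Among protein-coding genes it was 0.22, and 0.13 after sequence adjustment. The simulation gave Col the same scatter as the other columns, so it does not cover a Col column out of line. Col is a single pooled column that cannot be split, so part or all of the excess may come from it.

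**Figure D3:**
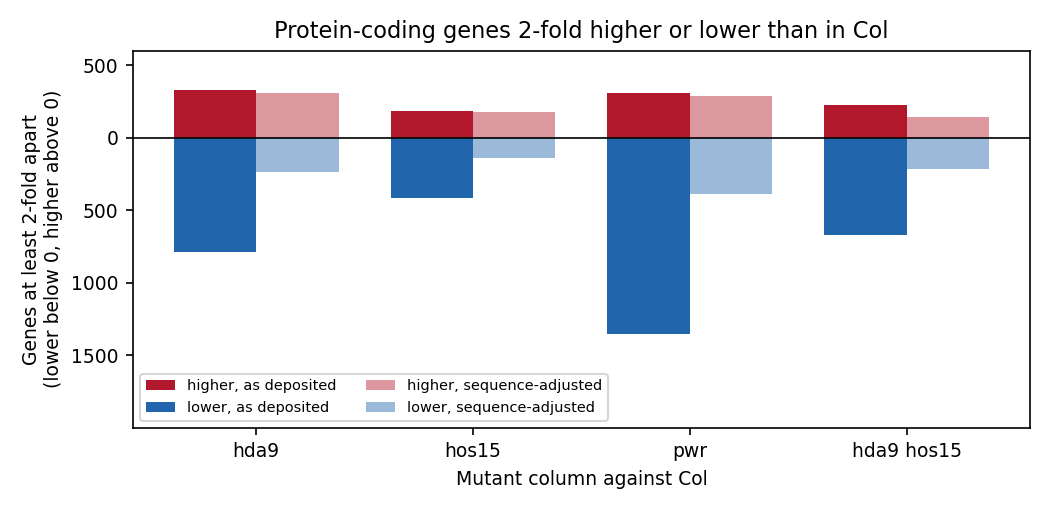
Number of protein-coding genes at least 2-fold higher (red, above 0) or lower (blue, below 0) than Col in each mutant, as deposited (dark) and sequence-adjusted (light). The lower counts shrink with adjustment, from 1355 to 385 in pwr, and the higher counts go from 310 to 287, of which 129 are the same genes.

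Of the gene lists fixed before the data were examined, the cold-response list stood high in all 4 mutants. As for every list, the 4 comparisons share the same Col column and are not independent. Low Col values of these genes alone would put the list high in all 4. Cold-response genes had median log2 fold changes of 0.66 in hda9, 0.82 in hos15, 0.80 in pwr and 0.95 in the double mutant, each at the 100th percentile, and 0.49, 0.69, 0.70 and 0.90 with sequence adjustment. Of 11 measured members, 3, 2, 3 and 5 were higher. COR15A, a cold-induced chloroplast protein gene, stood at 50.7 FPKM in Col and 159 in the double mutant, and COR15B at 162 and 484. COR47, a dehydrin gene, went the other way in pwr, at 120 FPKM against 296, a difference under 2-fold after adjustment. Abscisic acid and drought genes did not stand apart before adjustment (medians -0.17 to 0.05). With it they stood at 0.24 in hos15 (99.3rd percentile) and 0.27 in the double mutant (99.5th). CYP707A3, an enzyme of abscisic acid breakdown, was higher in hos15, at 14.8 FPKM against 5.36. NCED3 was higher in pwr and the double mutant, and RD29A and ERD10 were lower in pwr, at 11.3 and 27.5 FPKM against 26.1 and 69.1, a difference that adjustment removed.

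Salicylic acid and defence genes had medians of -0.27, -0.27, -0.44 and -0.43 in hda9, hos15, pwr and the double mutant, at the 19.6th, 7.63rd, 8.31st and 3.63rd percentile, and after sequence adjustment at the 1.15th, 5.06th, 1.73rd and 1.95th. PCC1 stood at 6.72 FPKM in Col and 1.25 to 2.58 in the mutants, and WRKY70 at 7.71 in Col, 2.35 in pwr and 2.08 in the double mutant. CBP60G went the other way in hda9, at 7.35 FPKM against 3.08 in Col, and stayed past 2-fold after adjustment. The jasmonate list, high in hda9, was low in the double mutant at -0.31 (0.55th percentile), where the repressor genes JAZ5 and JAZ7 were lower and AOS was higher, at 209 FPKM against 101. Defensins were also high in hos15 (median 0.16, 97.6th percentile), pwr (0.48, 100th) and the double mutant (0.25, 99.8th). With sequence adjustment they stayed so in hda9 and pwr, and were at the 91.8th percentile in hos15 and the 95.8th in the double mutant. NLR immune receptors, in the short fixed list and in the annotation family, had medians of -0.48 and -0.42 in pwr, and 0.12 and 0.14 after sequence adjustment. In hos15 the family median was -0.04, at the 98.4th percentile because matched lists were lower still. After adjustment the family lay at the 100th, 100th, 99.98th and 99.5th percentile in hda9, hos15, pwr and the double mutant, against the 0.09th in pwr before it, and the short list at the 99.99th in hos15. The heat shock family likewise went from -0.18 to 0.05 in hos15 and from -0.38 to 0.09 in pwr. The heat shock list had 4 measured members, of which HSP90.1 was lower in pwr, a log2 value of -1.03 that became 0.31 with sequence adjustment.

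The circadian list as a whole did not stand apart, but 4 members, PRR3, PRR7, LNK1 and LNK2, were lower in at least 1 mutant and no member was higher. PRR7 stood at 43.5 FPKM in Col, 17.8 in hda9, 22.9 in hos15, 13.7 in pwr and 15.3 in the double mutant, and LNK2 at 18.0, 7.50, 6.56, 5.43 and 4.83. LNK2, which overlaps an antisense gene, was the only one of 18 measured members past 2-fold in all 4 mutants, and stayed so after adjustment. Of the other 3, only PRR3 in pwr (log2 fold change -1.01) stayed past 2-fold. Flowering-time genes showed few differences. None of the 7 measured floral promoters, of 14 listed, was 2-fold apart in any mutant, SOC1 standing at 20.9 FPKM in Col and 11.3 in pwr. The floral repressors TEM1 and TEM2 were higher in hda9, at 55.1 and 64.0 FPKM against 24.8 and 27.4. MAF2 was just past 2-fold lower in pwr (14.5 against 30.1) and at a log2 value of -0.40 with sequence adjustment. In the floral organ identity list 2 of 9 genes were measured, and neither differed 2-fold.

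Among metabolic and growth lists, flavonoid genes in pwr had a median of -0.41 (6.22nd percentile, and 2.01st with sequence adjustment), with DFR at 0.763 and LDOX at 1.11 FPKM against 3.12 and 3.29. The LDOX difference was under 2-fold after adjustment. MYB51, a regulator of indolic glucosinolates, was higher in hda9 and hos15 (26.5 and 22.5 against 9.67 FPKM), and MYB76, of the aliphatic branch, lower in hda9 (1.06 against 3.53) and pwr (1.19). No other member of these 2 lists was 2-fold apart, and the aliphatic list in the double mutant had a median of 0.29 (97.9th percentile) after sequence adjustment. In the auxin, shade and warmth list IAA2 and IAA1 were lower in pwr and the double mutant, IAA2 was lower in hda9 too, and PIF5 was lower in the double mutant, at 12.1 FPKM against 27.5. The senescence list had SAG21 and SEN1 higher in hda9 and WRKY53 lower in pwr and the double mutant.

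The lists included markers of tissue composition. Nuclear photosynthesis genes had medians of 0.30, 0.23, 0.47 and 0.37 in the 4 mutants, between the 26.5th and 84.3rd percentile. After sequence adjustment they lay at the 0.62nd percentile in hda9, 1.63rd in hos15, 19.4th in pwr and 4.14th in the double mutant. Their adjusted medians were -0.03, -0.003, 0.12 and 0.10 in this order, against 0.16, 0.15, 0.21 and 0.24 for matched lists. Root tissue markers were at 0.33 in hda9 (99.8th percentile) and 0.19 in the double mutant (98.6th percentile), and at 0.02 and -0.08 after sequence adjustment. Their member MYB36 was lower, at 4.25 FPKM in Col, 1.47 in hos15 and 1.24 in pwr, and under 2-fold in both after adjustment. The 8 reference genes had medians of 0.36 to 0.48, at the 92.4th to 94.3rd percentile, none past 2-fold. Lists matched on expression had medians of 0.19 to 0.22. Seed maturation genes were nearly absent, with 2 of 20 measured, and PER1 was higher in the double mutant, at 2.53 FPKM against 0.360. SAUR genes had medians of 0.13 to 0.22, all at the 100th percentile, but -0.09 to -0.03 after adjustment. Core histones, cytochrome P450 genes, class III peroxidases and transposable element genes stayed inside the percentile bounds in all 4 mutants before adjustment. Of these, class III peroxidases lay at the 0.39th percentile in hos15, 1.00th in pwr and 0.42nd in the double mutant after adjustment. Cytosolic ribosomal protein genes reached the 97.7th percentile in the double mutant and the 88.0th after adjustment. They then lay at the 0.01st, 0.03rd and 2.15th in hda9, hos15 and pwr. Their adjusted medians in these 3 were positive, at 0.04, 0.04 and 0.10, and ranked low because matched lists had 0.13, 0.12 and 0.16. Xyloglucan endotransglucosylases were at the 99.8th percentile in hda9, and after adjustment at the 87.2nd there and the 0.11th in the double mutant.

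**Figure D4:**
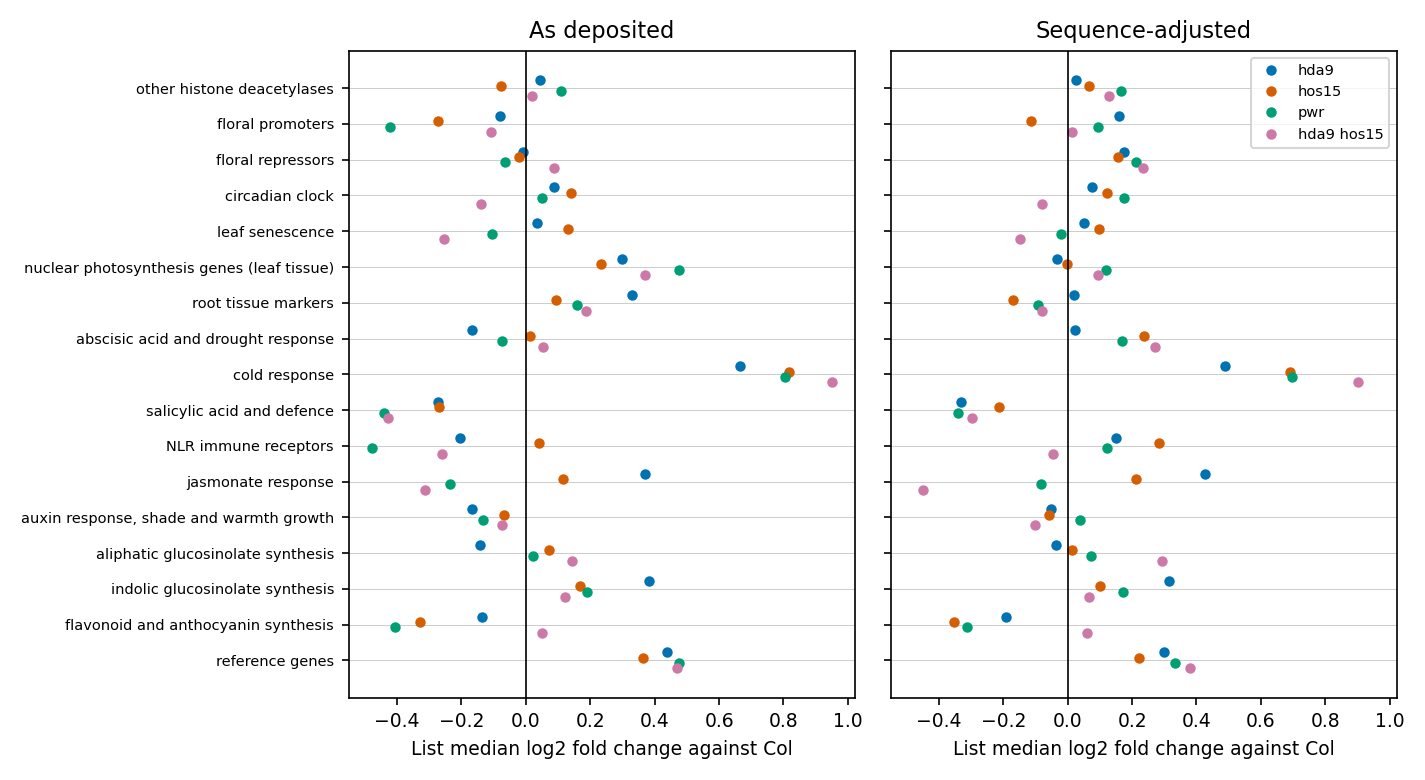
Median log2 fold change against Col (horizontal axis) of each fixed gene list with at least 5 measured members, 1 point per mutant, as deposited (left) and sequence-adjusted (right). The cold-response list lies highest in all 4 mutants on both sides, at 0.66 to 0.95 and 0.49 to 0.90, while the NLR list in pwr goes from -0.48 to 0.12.

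Many of the largest differences on the log2 scale were on rows of very short RNAs. AT1G28720 (72 nt) stood at 306 FPKM in hda9 and was listed at 0 in Col, pwr and the double mutant. AT2G07764 (72 nt) stood at 337 in Col and was listed at 0 in hda9, and the microRNA precursor row MIR394b (121 nt) stood at 14.5 in hda9, was higher still in pwr and was listed at 0 elsewhere. A longer noncoding RNA, AT2G24592 (483 nt), stood at 82.6 in Col and 26.5 in the double mutant and was listed at 0 in the single mutants. The fragments behind such values are unknown, and no fold is given for them.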

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

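The 3-fold threshold, the restriction to protein-coding transcripts of at least 300 nt and the sequence adjustment were chosen after seeing the data. No paired analysis was possible because the file gives 1 value per genotype and not the values per library. For the same reason the fits with only the genotypes compared, without a trend, with each library left out, with an adjusted p plus 2-fold, and with an estimated inter-gene correlation were not run. Counts of genes, in the order hda9, hos15, pwr and double mutant against Col, were 1226, 701, 1793 and 1020 as reported. Requiring a mean FPKM of 5 gave 687, 367, 1050 and 600, a 3-fold threshold 336, 188, 557 and 208, and sequence adjustment 545, 319, 672 and 359, against 1113, 602, 1665 and 900 for the same protein-coding genes unadjusted; a pseudocount of 0.1 gave 1107 in hos15 and 1638 in the double mutant. The double mutant against hda9 (350) gave 580 with the pseudocount of 0.1, 225 with the mean of 5 and 112 at 3-fold. Against hos15 (244) it gave 435 with that pseudocount, 82 at 3-fold and 155 with adjustment, where the restriction to protein-coding genes alone gave 165. For hda9 against hos15 (140), hda9 against pwr (175) and hos15 against pwr (227), the pseudocount of 0.1 gave 262, 390 and 659, the mean of 5 gave 89, 106 and 151, 3-fold gave 70, 63 and 62, protein-coding genes alone gave 56, 95 and 133, and adjustment gave 56, 78 and 59. The last pair gave 389 with a pseudocount of 0.5. Genes off the sum of the single mutants (1409) were 803 with the mean of 5, 513 at 3-fold and 939 with adjustment (1274 protein-coding before it). Genes shared by the 3 single mutants (497) were 793 with the pseudocount of 0.1, 256 with the mean of 5, 120 at 3-fold and 175 with adjustment (466 protein-coding before it). A stricter filter and threshold leave fewer genes by construction. With the mean of 5, lower calls against Col shrank more than higher calls. They were 389 lower and 298 higher in hda9, 195 and 172 in hos15, 743 and 307 in pwr, and 360 and 240 in the double mutant. For settings other than the stricter filter and threshold the cause was not tested. The median correlation (0.82) was 0.75 with the pseudocount of 0.1 and 0.89 among protein-coding genes. The 5 values of a targeted gene in its own mutants kept their side of 2-fold in all settings. HOS15 in hda9 and pwr did so in all but the sequence adjustment.

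Sequence adjustment also turned 12 results to the other side, of genes past 2-fold or lists past the percentile bounds. A gene was counted by the sign of its log2 fold change, a list by the side of its median from the median of matched random lists; plain sign changes of medians, such as SAUR in pwr (to -0.026) and the NLR family in hos15 (to 0.157), are therefore not among them. The cause was not tested beyond the adjustment itself. In pwr, ERD10 became 0.024, RD29A 0.14, RPP13 0.19 and HSP90.1 0.31, and the NLR list became 0.12, the NLR family 0.14 and the heat shock family 0.085. The heat shock family became 0.047 in hos15. The SAUR medians became -0.076 in hda9, -0.073 in hos15 and -0.092 in the double mutant, and root markers became -0.080 in the double mutant. It left 30 further values of named genes under 2-fold, among them PRR7 in hda9, pwr and the double mutant, AOS in hda9 and the double mutant, EDS1 in hda9 and pwr, JAZ5 and IAA1 in pwr and the double mutant, IAA2 in hda9, NCED3, COR47, MAF2, LDOX and MYB76 in pwr, and PDF1.2 in hos15 and pwr. It moved 20 list medians outside the percentile bounds and 6 inside. Under the pseudocounts, filters and scalings fixed before the data were examined no named gene past 2-fold and no list past the bounds turned to the other side. Under these, 31 values of named genes fell below 2-fold and 1048 did not, and 25 list medians moved outside the percentile bounds, 10 moved inside and 609 stayed. Depth is unknown, so its limits cannot be given.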

Other observations

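Tests against GC and length, against Col alone and of the HOS15 transcript were chosen after the result was seen; the rapid-response list was written after its pattern was noticed on other genes.

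A list of 22 genes that respond within minutes to touch or wounding, written without the genes named so far, had 21 measured members and described a group not covered by the fixed lists. Of these, 17 were higher in hda9, 12 in hos15, 9 in pwr and 1 in the double mutant. CAF1a, a deadenylase subunit gene, stood at 9.09 FPKM in Col, 36.1 in hda9, 30.1 in hos15, 26.6 in pwr and 9.95 in the double mutant. ERF11, an ethylene-response factor gene, stood at 3.03, 11.6, 8.45, 5.90 and 3.24 in the same order. The regulators WRKY33 and WRKY46 did not follow, WRKY33 with log2 fold changes of 0.22 in hda9, 0.37 in hos15, -1.14 in pwr and -1.34 in the double mutant, and WRKY46 with -0.25, 0.15, -0.69 and -0.72.

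One pattern is the loss of this rapid-response signal in the double mutant although both single mutants have it. A candidate explanation is a touch or wound response that differed between the harvested plants, for example through handling. It needed the unseen list to move as the first genes had, and it did: the list median was 1.32 in hda9 and 1.06 in hos15 (both at the 100th percentile), 0.78 in pwr, 0.07 in the double mutant, and -1.23 for the double mutant against hda9 (percentile 0). Transcript sequence is argued against as the whole cause, since after adjustment the hda9 median of 1.24 was still at percentile 100. The list cannot separate handling from genotype, so a dependence of these genes on HDA9 and HOS15 stays open and untested, and harvest records or the values per library would be needed.

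A further pattern is the set of 343 protein-coding genes that were 2-fold lower in all 4 mutants, of which 81.6% were over 54% purine, against 11.6% of all genes. A library bias against purine-rich transcripts may account for part of it, and would act where the protein is not concerned, as in untranslated regions. There the fold change went down with purine (partial rho -0.19, 95% bootstrap interval -0.20 to -0.18). It also went down with purine at codon position 3 (partial rho -0.28, -0.29 to -0.27) and at positions 1 and 2 (-0.21). Among 291 ribosomal protein genes rho with the purine percentage of the whole transcript was -0.44 (-0.52 to -0.35). A purine at position 3 can change the amino acid, and whole transcripts include all codon positions. The values that include coding sequence therefore do not set the protein aside. Intervals in this paragraph are over genes only. Genes are not independent, and no variation between libraries enters the intervals. GC content and length are argued against as the whole cause. After their removal 64.1% of the genes (Wilson 95% interval over genes 58.9 to 69.0) stayed lower, against 21.3% after removal of purine content. The set's median of the mean log2 fold change was -1.55 as deposited, -1.37 after removal of GC and length and -0.93 after purine. It was -0.77 after removal of all of these, with 14.3% of the genes still 2-fold lower in all 4. Genes picked as low stay low on average through the picking alone. The remainder therefore does not show a fall apart from sequence. Col alone out of line is argued against only as the source of the whole purine trend, since the trend also ran between hos15 and pwr (rho 0.49). Of the 343 genes, 337 were lower in pwr than in hos15, but they were picked as low in both, and pwr had the wider fold changes. Neither value bears on the fall common to all 4 mutants, part or all of which may lie in Col. Whether the genotypes act through sequence also stays open.

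Another pattern is the low HOS15 transcript in hda9 and pwr, which bears on whether loss of one partner lowers another. Its purine-rich sequence is a candidate explanation: among the 200 genes closest to it in purine content, highest purine window, length and GC, HOS15 was at the 16.5th percentile in both hda9 and pwr, inside their range. In hos15 and the double mutant it was at percentile 0. The log2 fold change of HOS15 was -1.68 in hda9 and -2.04 in pwr, below neighbour medians of -0.98 and -1.31. The 5th percentiles of the neighbours were -2.24 and -2.63, so a moderate further fall of HOS15 would go unseen. The neighbours had a median highest purine window of 85%, against 91% for HOS15, so the match is incomplete. A regulation of HOS15 by HDA9 and PWR was not tested and stays open.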
